A study of Arabidopsis thaliana with 11 samples.

How the data were processed

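RNA from seeds of Arabidopsis thaliana, 7 to 9 days after pollination, was sequenced in 11 libraries, per the labels' protocols. Every seed came from a cross between the ecotypes Columbia (Col) and Landsberg erecta (Ler), so that sequence differences tell the maternal from the paternal transcript. The endosperm, the nutritive tissue of the seed, and the embryo were separated by dissection, and endosperm was separated from the seed coat, which is maternal tissue.

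The deposited tables hold read counts: for each of 28523 genes, per the readme beside the files, the number of reads that matched the gene with fewer mismatches in Col than in Ler, and the reverse. Reads were aligned to cDNA models, per the same readme, with Bowtie, per the submitters' processing notes. The version of Bowtie, the annotation release, the use of strand and the treatment of reads that match several genes are not given in the sources used here. Reads without an ecotype difference are not in the tables, so every total below counts allele-assigned reads only, and a gene without a usable difference has no value. Near-identical or overlapping genes could share reads, and their values are uncertain. Of the gene identifiers, 27688 matched a locus tag in the TAIR10.1 gene table, which served only for symbols and for neighbouring genes. For 17936 of them the symbol is the identifier itself. The genome build behind the deposited counts is not named, and no coordinates are given.

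Groups were taken from the titles. Wild-type pure endosperm has 3 libraries (2 of Col × Ler, mother first, and 1 of Ler × Col), wild-type full endosperm has 2 (1 per direction), and wild-type embryo has 3 (2 of Col × Ler and 1 of Ler × Col). The labels do not say how "pure" and "full" preparations differ. The titles of pure endosperm replicate 1 and embryo replicate 1 carry "LCM", a usual abbreviation of laser capture microdissection, while their protocol text is that of the other libraries. A dme mother (Col × Ler), a fie mother (Ler × Col) and a met1 father (Ler × Col) gave 1 endosperm library each. Replicates are numbered in accession order. The labels do not say whether replicates came from separate plants, so p-values measure only the spread between these libraries, which can be technical. Libraries of 1 group differed by far more than sampling noise (chi-square per degree of freedom from 13.7 to 59.5 over the 7 pairs), and none was counted as a repeat of another.

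Columns were renamed maternal and paternal by the direction of the cross. All 11 libraries were fitted together with edgeR 4.0.16 in R 4.3.3 (robust quasi-likelihood fit and test). Each gene had 1 term per library, Col-against-Ler allele terms for endosperm and for embryo, and a parent-of-origin term per group. Genes needed at least 10 allele-assigned reads summed over the libraries of each cross direction of the groups compared. Endosperm carries a double maternal and a single paternal genome dose, so its parent term was tested against a maternal share of 66.7%, and that of embryo against 50%. Log2 values of parental bias are maternal over paternal reads relative to these shares. A mutant was compared with wild-type pure endosperm through the difference of their parent terms. A mutant group of 1 library was assumed to vary as the wild-type libraries do, which cannot be checked. Each mutant has only 1 cross direction, so its parent term relies on the Col-against-Ler allele term shared by all endosperm groups. An ecotype effect that differs in a mutant cannot be told apart from a change in parental bias. Tissues were compared on the summed counts of both alleles with edgeR (TMM, filterByExpr) and the set of libraries named alike as a block (LCM-titled Col × Ler, other Col × Ler, Ler × Col). Calls have a Benjamini-Hochberg adjusted p under 0.05.

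Before the data were examined, the groups, designs, tests, 12 gene lists, the rule for named genes and the alternatives were fixed, except 1 alternative named below. The rule took, per comparison, the 10 genes with the smallest p in each direction whose libraries with at least 10 reads lay on 1 side, up to 4 called members of each list, the literature lists of imprinted genes, the 3 mutated genes and, for mutants, the 10 wild-type biased genes with the smallest p in each direction. A strong bias was a maternal share of at least 85%, or at most 50%, in each pure library with at least 10 reads. The lists (literature maternally and paternally expressed genes, seed coat, endosperm, embryo, storage reserve, photosynthesis, Polycomb PRC2, DNA methylation, type I MADS, HD-ZIP IV, cell cycle) were tested with fry and camera (limma 3.58.1), camera with a preset correlation of 0.01 and with an estimated one, where at least 3 members were measured. Some genes that the rule names are not reported here. Mean maternal shares leave out libraries with under 10 reads of the gene.

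Alternatives were minimum counts of 30 and 1, DESeq2 1.42.0, the median ratio as the expected ratio, fewer libraries in the fit, the LCM-titled libraries or each wild-type library left out, exact binomial and Fisher tests, biased genes taken from full endosperm, DESeq2 size factors, no count filter, no block, and full in place of pure endosperm. After the data had been seen, full endosperm was also used as the wild type for the mutants. The exact 95% intervals (Clopper-Pearson) of single libraries cover counting error only.

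The fits were tested on simulated counts with real means and library sizes and 200 changed genes. The simulated spread between libraries was a fixed setting, not taken from the data. Changes were set equally in both directions, without a shift of most genes. The shares below are therefore not the error rates of the real comparisons. In the pure endosperm comparison, 39% of 187 tested changed genes were recovered at a 2-fold change, 85.6% of 187 at 4-fold and 98.4% of 185 at 8-fold, with 1, 7 and 13 false calls. In the dme comparison the shares were 3.7%, 53.2% and 70.7%, in the fie comparison 0%, 45.1% and 73.5%, and in the met1 comparison 2.2%, 33.2% and 63%. Between tissues they were 0%, 81% and 90.5%. For embryo they were 34.6%, 91% and 100%, for full endosperm 35.2%, 81.9% and 96.9%, and for the difference between endosperm and embryo 14.6%, 71.8% and 95.7%.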

Results

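Parental expression was measured in seeds of reciprocal Col × Ler crosses, to ask which genes of the endosperm are expressed mainly from the maternal or the paternal genome, as in genomic imprinting. Allele-assigned reads per library ranged from 358142 in pure endosperm replicate 1 to 4828301 in full endosperm replicate 2. The pure endosperm libraries held 358142, 2700162 and 2840412 reads, the full endosperm libraries 4562509 and 4828301, and the embryo libraries 607800, 2446825 and 808102. The dme library held 4675761, the fie library 3766443 and the met1 library 1057104. The maternal share of all reads was 67.4%, 69.5% and 66.9% in pure endosperm, 73.7% and 71.5% in full endosperm, and 52.2%, 52.9% and 49.4% in embryo. It was 88.9% in the dme library (exact interval 88.87% to 88.92%), 77.3% in the fie library and 73.6% in the met1 library.

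**Figure D1:**
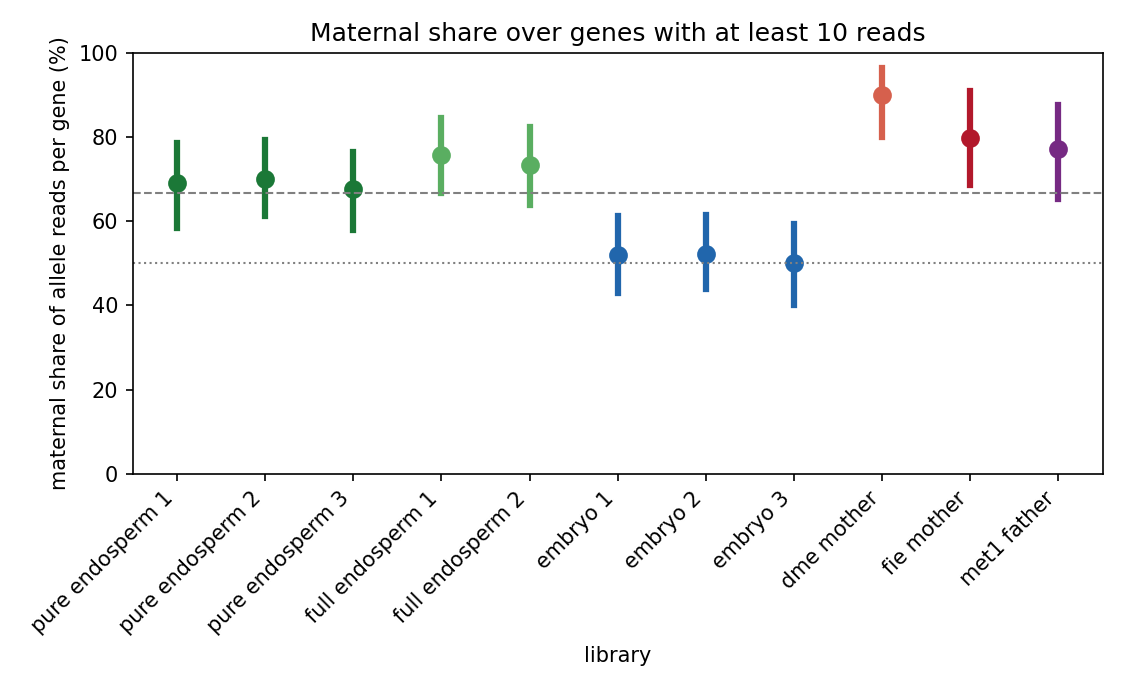
Median maternal share of allele reads per gene in each library (points, %) with the range from the lower to the upper quartile (bars), over genes with at least 10 reads. The dashed line marks 66.7% and the dotted line 50%; embryo medians lie between 50% and 52.3%, pure endosperm between 67.6% and 70%, and the dme library at 89.9%.

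Tissue markers set the libraries apart. The extensin-like gene EPR1 (AT2G27380), whose similar neighbours make its counts uncertain, took 8.62% and 13.1% of the reads of pure endosperm replicates 2 and 3, 20.7% and 14.4% in full endosperm and 18.7% in the met1 library. It took 1.18% in the LCM-titled endosperm library, 0.0451% in the dme library and 0.00735% in the fie library. TT10 (AT5G48100), a laccase of the seed coat, had 452, 2900 and 1490 CPM (allele reads scaled to equal library totals) in pure endosperm, 10700 and 7560 in full endosperm, 39700 in the dme library, 19400 in the fie library and 9630 in the met1 library. The seed coat list of 25 genes summed to 1463, 5200 and 2686 CPM in pure endosperm, to 14196 and 9937 in full endosperm, and to 57044 CPM in the dme library, 25120 in the fie library and 13421 in the met1 library.

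**Figure D2:**
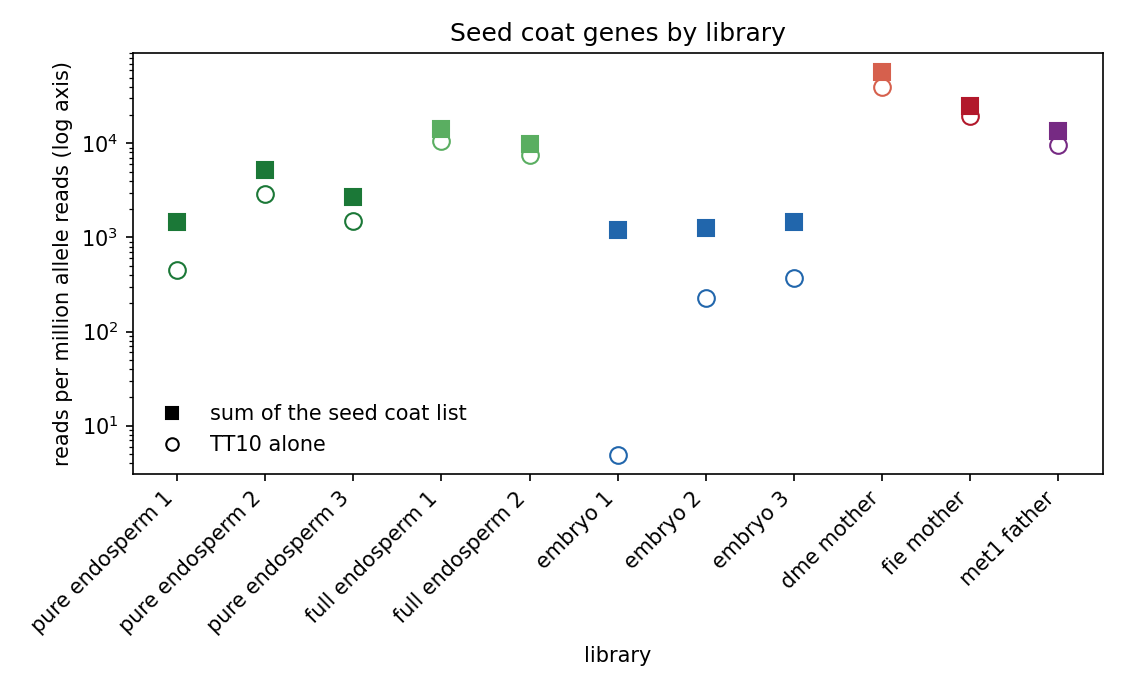
Summed expression of the seed coat list (squares) and of TT10 alone (circles) in each library, in CPM of allele reads on a log axis. The list sums lie between 1193 and 1447 CPM in embryo, between 1463 and 5200 in pure endosperm, and at 57044 in the dme library.

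The mutated genes were examined first as a check of the labels. DME (AT5G04560), a DNA glycosylase that removes DNA methylation, had 165 ± 71.3 CPM in pure endosperm (SD, n = 3), 60.7 CPM in the dme library, 45.4 in the fie library and 71.9 in the met1 library. FIE (AT3G20740), a Polycomb subunit, had no allele-assigned read in any library, and whether it has a usable ecotype difference is not known. MET1 (AT5G49160), the maintenance DNA methyltransferase, had 2 reads in the met1 library and 0.931 ± 1.61 CPM in pure endosperm (SD, n = 3). These values check none of the 3 labels, since a mutant allele can still be transcribed.

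Which genes of pure endosperm depart from the 2 maternal to 1 paternal genome dose was asked first. The neighbouring genes AT1G62060, AT1G62070 and AT1G62080 had maternal shares of 99.9% ± 0.0928 (SD, n = 2), 99.9% ± 0.0957 (SD, n = 3) and 99.8% ± 0.00503 (SD, n = 2), values that are uncertain where neighbours share reads. Genes of seed coat pigment and mucilage followed, with TT8 (AT4G09820), a bHLH regulator, at 99.7% ± 0.366, the galactosidase MUM2 (AT5G63800) at 99.8% ± 0.0206 and the homeobox gene GL2 (AT1G79840) at 98.1% ± 0.576 (SD, n = 2 each). The LCM-titled library, the shallowest, held 7 maternal reads of TT8, 7 of MUM2 and 8 of GL2, and no paternal read of them. Of genes known as maternally expressed, all 3 libraries held the F-box gene SDC (AT2G17690) at 99.4% ± 1.05, the homeobox gene HDG9 (AT5G17320) at 96.6% ± 1.4 and MYB3R2 (AT4G00540) at 100% ± 0 (SD, n = 3 each). AT1G59930 was at 99.9% ± 0.124 (SD, n = 3).

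Paternally biased genes included several of DNA methylation. VIM5 (AT1G57800), of the SRA-domain family that binds methylated DNA, had a maternal share of 7.17% ± 0.468 (SD, n = 3), with log2 = -4.67 ± 0.21 (SE) and adjusted p = 2e-41 in edgeR after Benjamini-Hochberg adjustment. VIM1 (AT1G57820) was at 44.3% ± 17.7, the demethylase ROS1 (AT2G36490) at 44.4% ± 20.5 and SUVH9 (AT4G13460) at 45.8% ± 19.4 (SD, n = 3 each), with wide spreads between libraries. For ROS1 the maternal and paternal reads were 16 and 47, and 161 and 225, in Col × Ler. In Ler × Col they were 267 and 137, near the genome dose. In exact binomial tests that had to hold in both cross directions, the calls of VIM1, ROS1 and SUVH9 were lost. The call of VIM5 held in all alternatives. VIM1 and VIM5 lie close together and are similar, so their counts are uncertain. The auxin synthesis gene YUC10 (AT1G48910) was at 27.4% ± 32 (SD, n = 2), AT3G14205 at 28.7% ± 2.69 and AT2G36560 at 4.55% ± 7.87 (SD, n = 3 each). AT5G63740 was at 10.5% ± 1.14 (SD, n = 2), and the MADS gene AGL92 (AT1G31640) had no maternal read among 12 in replicate 3, the 1 library with at least 10. The homeobox gene HDG3 (AT2G32370), known as paternally expressed, had 125 maternal and 45 paternal reads in the LCM-titled library but 42 and 122, and 21 and 116, in the other 2, and was not called in edgeR with all libraries (log2 = -2.18, adjusted p = 0.625). Over 15 alternatives its adjusted p ran from 9.44e-18 without the LCM-titled libraries to 0.96 without pure replicate 3, and it was called paternal in several of them, DESeq2 included.

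Of 7327 genes tested in pure endosperm, 308 were called maternal and 45 paternal, and 201 and 19 of them had a strong bias in each measured library. Of 15 seed coat genes measured, 9 were called maternal (12 adjusted over the list alone). The list stood above other genes in camera (adjusted p = 6.59e-15), but adjusted p = 0.165 with an estimated correlation. All 3 measured genes of the literature maternal list were called maternal, also adjusted over the list alone (adjusted p = 0.114 with an estimated correlation). Of the literature paternal list 3 of 5 were called paternal, with 3 paternal and 1 maternal adjusted over the list alone (adjusted p = 0.165 with an estimated correlation). Of 16 DNA methylation genes 4 were called paternal, the same number adjusted over the list alone (adjusted p = 0.165 with an estimated correlation). The HD-ZIP IV list had 2 maternal genes of 8, the embryo list 1 of 8, and type I MADS 1 paternal gene of 1, each also adjusted over the list alone. No member was called by edgeR of 5 endosperm, 6 storage reserve, 11 photosynthesis and 3 cell cycle genes (0 at an unadjusted p under 0.05 in each), nor of 3 Polycomb genes (1 at an unadjusted p under 0.05), and the same held adjusted over the list alone.

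Single libraries decided many of these calls. Without pure replicate 2 there were 48 maternal and 14 paternal calls (23 and 4 with a strong bias). Part of this drop is genes that fell under the read minimum: of 30 named genes called, 15 could still be tested, and 2 of these lost the call. Without replicate 3, the 1 pure library of Ler × Col, there were 180 maternal calls (113 and 8 genes with a strong bias). Of the 30 named genes called, 9 then lost the call, among them HDG9 (adjusted p = 0.216, from 1.7e-14 to 0.216 over the alternatives), MYB3R2 (1, from 1.48e-05 to 1), AT1G59930 (1, from 6.51e-58 to 1), YUC10 (0.359, from 8.85e-06 to 0.691), AT2G36560 (1, from 1.37e-16 to 1), AGL92 (1, from 1.02e-06 to 1) and SUVH9 (0.295, from 2.64e-06 to 0.447). All of these genes kept the sign of their log2 without replicate 3. It was then 4.65 for HDG9 (3.85 with all libraries), 5.12 for MYB3R2 (6.91) and 9.07 for AT1G59930 (9.4). It was -1.92 for YUC10 (-2.87), -8.73 for AT2G36560 (-5.82), -5.32 for AGL92 (-5.7) and -0.91 for SUVH9 (-1.31). The call of ROS1 was lost without replicate 2 (adjusted p = 0.125, from 0.000274 to 0.942). That of GSO2 (AT5G44700), the 1 called gene of the embryo list, was lost in most alternatives, DESeq2 included (adjusted p = 0.176). DESeq2 called 155 maternal and 28 paternal genes.

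Whether the full endosperm preparation shows the same biased genes was asked next. The median log2 over its 9174 tested genes was 0.48, against 0.07 in pure endosperm. TT10 had a maternal share of 99.7% ± 0.115 and AT1G12010 one of 99.8% ± 0.0574 (SD, n = 2 each). VIM5 was again paternal at 9.89% ± 1.97, as were YUC10 at 20.4% ± 14, AT2G36560 at 0% ± 0 (17 and 23 reads, none maternal) and AT1G60410 at 16% ± 0.907 (SD, n = 2 each). AT5G63740 stood at 68.8% ± 0.573 (SD, n = 2), where pure endosperm had 10.5%. This difference was not tested, and it rests on few reads. In the Ler × Col full library the maternal CPM of the gene was not above the 2.46 of pure replicate 3. The small SD therefore does not show a precise share. Of the seed coat list 15 of 18 measured genes were called maternal, also adjusted over the list alone (camera adjusted p = 1.13e-11, and adjusted p = 0.141 with an estimated correlation).

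In total 1827 genes were called maternal and 43 paternal in full endosperm by edgeR. With the median ratio in place of the genome dosage, the calls split into 813 maternal and 270 paternal. Of 304 genes called maternal in pure endosperm and tested here, 295 were called maternal again, and of 42 called paternal, 18 were called paternal again. With 1 library per direction, leaving out replicate 1 left 513 and 27 calls, and leaving out replicate 2 left 442 and 10. Without replicate 2 the calls of AT2G36560 (adjusted p = 1, from 2e-17 to 1 over the alternatives) and AT1G60410 (1, from 6.23e-10 to 1) were lost, and without replicate 1 that of YUC10 (0.314, from 1.43e-22 to 0.314).

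Whether parental bias is found in the embryo, which has equal parental doses, was tested in 3 libraries, and the median log2 was 0.05. The genes called maternal were led by those of the endosperm comparison: AT1G23200 at 99.5% ± 0.677, AT1G62060 at 99.7% ± 0.402 and AT1G62070 at 99.8% ± 0.00557 (SD, n = 2 each). All 3 were nearly absent from the LCM-titled embryo library, which had 0, 0 and 1 maternal reads of them. The endosperm gene EPR1 had a maternal share of 66.5% ± 4.01 in embryo (SD, n = 2; log2 = 1.02, adjusted p = 8.77e-05). This share is near the 66.7% expected in endosperm. EPR1 took 0.122% and 0.878% of the reads of embryo replicates 2 and 3, and 0.000494% in the LCM-titled embryo library. TT10 had 228, 369 and 4.94 CPM in these libraries. RNA of endosperm or seed coat in embryo replicates 2 and 3 was not tested as a source. The calls of EPR1 and TT10 therefore do not show a bias of the embryo itself. VIM5 was called paternal, with 9 maternal and 32 paternal reads in replicate 2 and 3 and 37 in replicate 3. Its expression was 45.9-fold higher in pure endosperm than in embryo, so endosperm RNA is not excluded for VIM5. This call therefore does not show a bias of the embryo itself either.

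Of 5447 genes tested in embryo, 43 were called maternal and 1, VIM5, paternal. Of the 43, 29 were also called maternal in pure endosperm. Called members of the fixed lists were TT10 and MUM2 of 9 seed coat genes (3 adjusted over the list alone), EPR1 and ALE1 of 4 endosperm genes (2 adjusted over the list alone), and VIM5. The log2 of ALE1 was 0.98, near the 1.02 of EPR1, so endosperm RNA is not excluded for ALE1 either. Of 10 embryo genes edgeR called 0, also adjusted over the list alone, and 0 at an unadjusted p under 0.05. No list was called by camera with either correlation. Without embryo replicate 2 there were 2 maternal and 0 paternal calls in edgeR, and without any 1 of the other libraries that could be left out, 2 or 3 paternal calls. Without embryo replicate 2, 1 of the 15 named genes called had enough reads to be tested, so most calls were not tested again. The call of ALE1 was lost without embryo replicate 1 (adjusted p = 0.224) and without replicate 2 (0.93, from 0.00608 to 0.93 over the alternatives), and DESeq2 did not call EPR1 (0.693, from 1.46e-49 to 0.693) or MUM2 (0.606, from 1.12e-05 to 0.606).

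Whether bias differs between endosperm and embryo was tested directly. GL2 was at 98.1% in pure endosperm and at 60% ± 2.63 in embryo (SD, n = 3; log2 difference 4.14 ± 0.35 (SE), adjusted p = 2.15e-10). The cuticle transporter ABCG12 (AT1G51500) was at 98.7% ± 1.84 against 53.6% ± 34.2 (SD, n = 2 each), BEL10 (AT1G19700) at 99.4% ± 0.786 (n = 2) against 51.8% ± 22.3 (n = 3), and the phenylpropanoid repressor MYB4 (AT4G38620) at 98.1% ± 2.72 (n = 2) against 46.9% ± 18.4 (n = 3). Less maternal in endosperm were AT3G14205, at 28.7% against 61.8% ± 8.42 (n = 3), and ULP1D (AT1G60220), at 32.1% ± 19.9 against 51.5% ± 13.1 (n = 3 each). The difference for VIM5 was not called in edgeR (log2 = -1.93, adjusted p = 0.259) but was called in DESeq2 (0.0499, from 0.0499 to 0.366 over the alternatives), and in edgeR when adjusted over the literature paternal list alone, of which it was the 1 gene measured.

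Of 5115 genes, 47 were more and 13 less maternal in endosperm than in embryo in edgeR. The 13 included EPR1 (log2 = -1.14, adjusted p = 0.00324, but 0.832 in DESeq2), for which endosperm RNA in the embryo libraries is not excluded. The seed coat list had 3 of 8 measured members among the former, also adjusted over the list alone (camera adjusted p = 0.000559, and adjusted p = 0.645 with an estimated correlation). Without pure replicate 2 only 7 genes differed, without embryo replicate 2 there were 30, and without full endosperm replicate 1 or 2 there were 93 or 92. The call of ULP1D was lost without pure replicate 2 (adjusted p = 0.0508, from 0.00108 to 0.0508 over the alternatives).

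Whether maternal DME is needed for parental bias was asked with seeds of a dme mother. More maternal than in wild type were POM1 (AT1G05850), a chitinase-like gene of cell wall growth, at 99.6% (exact interval 99.4% to 99.8%) against 72.9% ± 9.25 in pure endosperm (SD, n = 3), and SUS1 (AT5G20830), a sucrose synthase, at 99% (98.7% to 99.2%) against 63.2% ± 21.5 (SD, n = 3). Paternally biased genes changed as well. VIM5 rose from 7.17% to 60.6% (58.2% to 62.9%), with log2 = 4.36 ± 0.37 (SE) and adjusted p = 5.27e-18. AT3G14205, picked here after its value was seen, was at 86.4% (84.5% to 88.1%), and ROS1 at 87.8% (84.6% to 90.6%). In the other direction, AT4G18150 fell from 99.6% ± 0.479 (SD, n = 3) to 34.5% (17.9% to 54.3%) on 29 reads, and the seed storage gene CRA1 (AT5G44120) was called less maternal at 55.8% (49.2% to 62.4%) against 76.8% ± 19.8 (SD, n = 3). In CPM the seed coat list was at 57044, which is 11 times the 5200 of pure endosperm replicate 2, of the same cross (1463 in the LCM-titled pure library, also of that cross). The embryo list was at 1617 CPM, against 546 and 271 in these 2 pure libraries and 984 in full endosperm replicate 1. Its median maternal share in dme was 78.1% over 11 genes. RNA of the embryo, which has equal parental doses, was not tested as a source of less maternal genes such as CRA1.

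Of 6980 genes, 3491 were more maternal and 61 less in dme than in wild type in edgeR, with a median log2 of 1.72. With the median ratio as the expected ratio the split was 515 and 550. Relative to that median, VIM1 (log2 = 1.5 to -0.36), DME (1.52 to -0.34), YUC10 (1.58 to -0.30) and AGL92 (0.84 to -0.99) turned direction. Of the 39 paternally biased genes tested, which were picked on the same pure libraries, 18 were more maternal and 1 less, and with the biased genes taken from full endosperm, 9 of 33. With the median ratio 7 paternally biased genes were more maternal and 39 maternally biased ones less. Of 304 maternally biased genes 101 were more and 9 less maternal, with the latter at 3 without pure replicate 2 and 5 without pure replicate 3 or either full endosperm library. With full endosperm as the wild type, 2562 genes were more and 78 less maternal, and of 36 paternally biased genes 12 were more and 4 less maternal. Of 6 storage reserve genes 3 were less maternal, also adjusted over the list alone (camera adjusted p = 9.7e-08, and adjusted p = 0.103 with an estimated correlation). Of these the calls of OLEO3 (adjusted p = 0.106, from 1.65e-24 to 0.106 over the alternatives) and OLEO4 (AT3G01570; 0.111, from 3.63e-08 to 0.111) were lost with full endosperm as the wild type, and also without the LCM-titled libraries (0.0812 and 0.0852). Of 16 DNA methylation genes 7 were more maternal, the same number adjusted over the list alone, but with the median ratio the calls of VIM1, SUVH9 and DME were lost. Below other genes in camera were also the literature maternal list and 11 photosynthesis genes (median log2 0.1, mean -0.09), each with 0 called by edgeR (1 and 0 at an unadjusted p under 0.05) and adjusted p = 0.103 with an estimated correlation. Without pure replicate 2, 1871 genes changed.

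Whether the Polycomb complex is needed was asked with seeds of a fie mother. POM1 was at 99.7% (exact interval 99.5% to 99.8%) against 72.9% in pure endosperm (log2 = 6.12, adjusted p = 5.69e-17), and MUM2 was less maternal at 97.8% (97.1% to 98.3%; log2 = -3.97, adjusted p = 0.00137). This call of MUM2 was lost with full endosperm as the wild type (log2 = -1.13, adjusted p = 0.285, from 0.000106 to 0.285 over the alternatives) and in DESeq2 (0.271). VIM5 rose to 48.5% (47.4% to 49.6%; log2 = 3.51 ± 0.38 (SE), adjusted p = 4.44e-11). Of 3 further genes paternal in pure endosperm, picked here after their values were seen, AT5G63740 had 11420 maternal and 12497 paternal reads, a maternal share of 47.7% (47.1% to 48.4%), with 6350 CPM against 13.9 ± 7.04 in pure endosperm (SD, n = 3). AT2G36560 was at 78.4% (75.8% to 80.9%) and AT1G60410 at 64.7% (61.4% to 67.9%). AGL92 was at 53.4% (47.4% to 59.3%). The maternal genes SDC, at 97.4% (92.5% to 99.5%), and HDG9, at 96.5% (94.2% to 98%), were not called changed. The bHLH gene ZOU (AT1G49770) had 52 maternal and no paternal reads (93.2% to 100%).

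Of 6728 genes, 1322 were more maternal and 42 less in fie in edgeR, with a median log2 of 0.92 (506 and 122 with the median ratio as the expected ratio). The seed coat list was at 25120 CPM, against 2686 in the pure library of the same cross. The embryo list was at 1544 CPM, against 425 in that pure library, with a median maternal share of 71.9% over 8 genes in fie. Embryo RNA was not tested as a source of less maternal genes here either. Of 37 paternally biased genes tested, 26 were more maternal and 1 less, but 15 without pure replicate 2 and 15 with the median ratio, where 19 maternally biased genes were less maternal. With full endosperm as the wild type 16 of 35 were more and 1 less maternal, over a total of 861 more and 102 less maternal genes, and with the biased genes taken from full endosperm 9 of 28. Of 305 maternally biased genes 73 were more and 12 less maternal, with the latter at 5 without pure replicate 2. Of the literature paternal list 3 of 4 measured genes were more maternal, also adjusted over the list alone (camera adjusted p = 0.0303, and adjusted p = 0.3 with an estimated correlation). Of 6 storage reserve genes 3 were less maternal, also adjusted over the list alone (adjusted p = 0.29 with an estimated correlation). Without pure replicate 3 the calls of OLEO1 (log2 = -0.52, adjusted p = 0.502, from 3.74e-74 to 0.502 over the alternatives) and OLEO2 (0.0536, from 5.53e-06 to 0.0536) were lost, and with full endosperm as the wild type that of OLEO4 (0.0618, from 0.00013 to 0.0618). The median log2 of 9 photosynthesis genes was -0.29 and their mean 0.34 (adjusted p = 0.46 with an estimated correlation). The calls of YUC10 (adjusted p = 0.33, from 1.09e-07 to 0.564 over the alternatives) and AGL92 (1, from 0.000658 to 1) were lost without pure replicate 3. Without pure replicate 3, 858 genes changed, and without replicate 2, 906.

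Whether DNA methylation of the paternal genome is needed for parental bias was asked with seeds of a met1 father. AT1G59930 fell from 99.9% ± 0.124 (SD, n = 3) to 51.7% (exact interval 46.6% to 56.7%), with 202 maternal and 189 paternal reads, log2 = -11.6 ± 1.16 (SE) and adjusted p = 2.67e-08. SDC, a gene silenced by DNA methylation, fell from 99.4% to 27.5% (19.7% to 36.4%), with 33 and 87 reads, and AT4G31060 from 97.8% ± 3.75 (SD, n = 3) to 42.1% (32.6% to 52%). The LOB-domain gene JLO (AT4G00220) went from 99.3% ± 0.646 to 72% (64.4% to 78.8%), and EIN2 (AT5G03280), of ethylene signalling, from 86.5% ± 6.05 (SD, n = 3 each) to 66% (59.5% to 72%). VIM5 stayed paternal, at 3.91% (1.89% to 7.07%; log2 = -1, adjusted p = 0.338). TT10 was at 99.6% (99.5% to 99.7%) and GL2 at 99.3% (98.1% to 99.8%).

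Of 5717 genes, 139 were more maternal and 22 less in met1 in edgeR, with a median log2 of 0.63 (40 and 32 with the median ratio as the expected ratio). The seed coat list was at 13421 CPM, against 2686 in the pure library of the same cross, and the embryo list at 1270 against 425. Of the 291 maternally biased genes tested 14 were less and 15 more maternal, and of 31 paternally biased genes 4 were more maternal (2 with the median ratio). With full endosperm as the wild type, 11 genes were more maternal and 18 less, 12 of them maternally biased in pure endosperm. No list was called by fry or camera. Without pure replicate 3, the 1 pure library of the same cross, 100 genes changed and 6 of the maternally biased genes were less maternal. Without full endosperm replicate 1 or 2, 282 or 281 genes changed. The calls of AT1G59930 (adjusted p = 1, from 2.25e-61 to 1 over the alternatives), SDC (0.0712, from 7.03e-19 to 0.0712), JLO (0.0636, from 1.33e-24 to 0.0636) and EIN2 (0.076, from 1.27e-19 to 0.076) were lost without pure replicate 3. DESeq2 did not call AT1G59930. It gave no adjusted p for AT4G31060 and SDC, whose log2 there was -5.52 and -8.66.

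**Figure D3:**
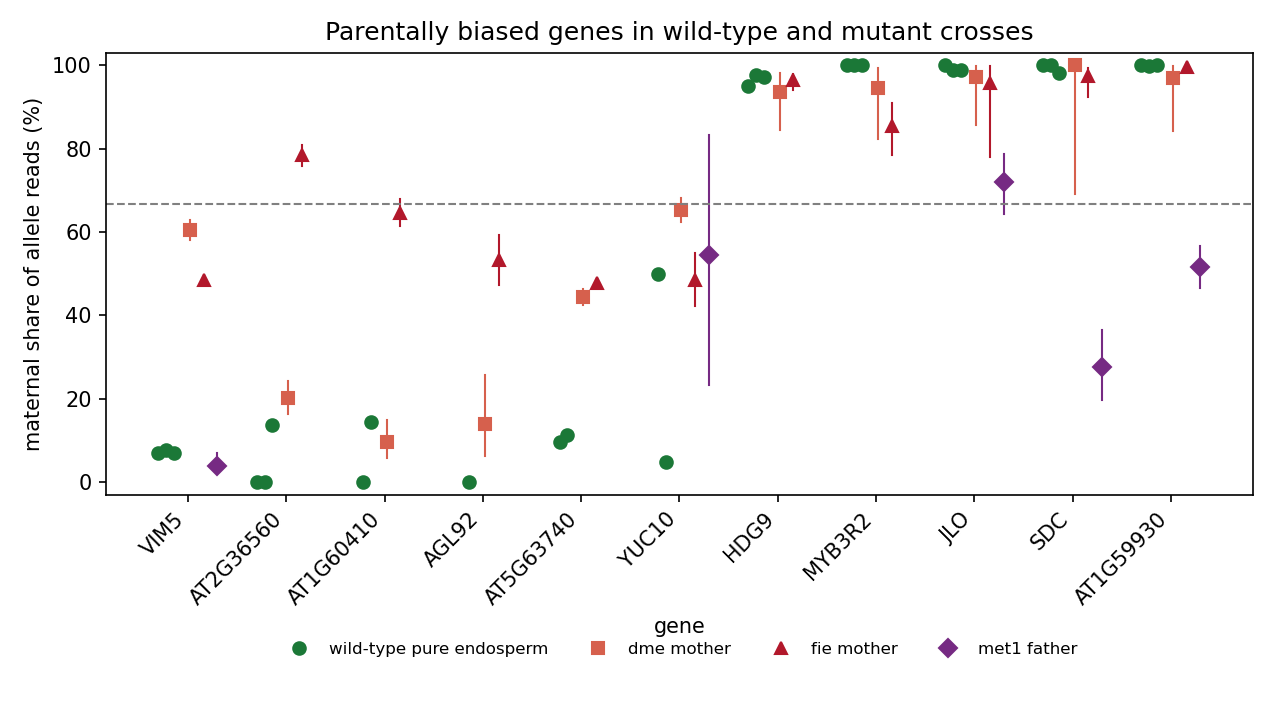
Maternal share of allele reads (%, y axis) of 11 genes biased in wild-type endosperm (x axis) in the pure endosperm libraries with at least 10 reads (green circles) and in the dme, fie and met1 libraries, with exact 95% intervals as bars. The dashed line marks 66.7%. VIM5 lies at 60.6% in the dme library and 48.5% in the fie library, and SDC at 27.5% in the met1 library.

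Which genes are expressed at different levels in endosperm and embryo was asked with the summed reads of both alleles. Higher in endosperm were EPR1 (76300 ± 60200 CPM against 3340 ± 4760), ALE1 (AT1G62340), a protease of the embryo surrounding endosperm (2250 ± 1940 against 82.1 ± 61.7), ZOU, a regulator of endosperm breakdown (260 ± 258 against 4.39 ± 2.9), and the cytokinin synthesis gene IPT6 (AT1G25410; 786 ± 521 against 15.6 ± 15.5; SD, n = 3 per tissue throughout). Of genes in the literature lists, VIM5 (45.9-fold), HDG3 (49.1-fold), SDC (36.6-fold) and HDG9 (23.7-fold) were also higher in endosperm. With full in place of pure endosperm the calls of HDG3 (log2 = 0.93, adjusted p = 0.453, from 1.32e-22 to 0.453 over the alternatives) and HDG9 (log2 = 0.84, adjusted p = 0.45, from 2.3e-13 to 0.45) were lost. Higher in embryo were the bZIP gene PAN (AT1G68640; 128 ± 86 CPM against 2.87 ± 0.798), the epidermal gene PDF1 (AT2G42840; 31.7-fold) and the replication clamps PCNA1 (AT1G07370; 4.49-fold) and PCNA2 (AT2G29570; 2.58-fold). VIM1 was 4.46-fold higher in embryo, against the direction of VIM5. Seed coat genes were higher in endosperm libraries, TT8 by 11.5-fold and TT10 by 17-fold.

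Of 7329 genes, 1001 were higher in endosperm and 991 in embryo in edgeR. Of the endosperm list 4 of 5 measured genes were higher in endosperm, also adjusted over the list alone, and of 11 embryo genes 9 were higher in embryo (9 adjusted over the list alone, with 2 then higher in endosperm). Of 12 seed coat genes 7 were higher in endosperm and 1 in embryo, the same numbers adjusted over the list alone. These lists have adjusted p = 0.394 with an estimated correlation. Without the block, 719 and 622 genes were called, without EPR1 (adjusted p = 0.119, from 3.15e-14 to 0.119 over the alternatives) and TT10 (0.093, from 2.27e-16 to 0.093). Without pure replicate 2 the counts were 555 and 460, and without embryo replicate 2 they were 641 and 489, and the call of PCNA2 was lost in both (adjusted p = 0.116 and 0.085, from 0.00278 to 0.116 over the alternatives). Without pure replicate 1 they were 1639 and 1500, and without embryo replicate 1 there were 1653 genes higher in endosperm.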

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

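The tests of the LCM-titled library, of the gain of maternal reads, of the shift of most genes in dme, of self-pollination and of the splits were chosen after the results were seen. The first pattern is the maternal bias itself. The bias of 60 genes differed between pure endosperm and embryo by a test of the difference, and the more maternal ones in endosperm included GL2 and MUM2 of the seed coat list, and TT4, whose call was lost without pure replicate 3 (adjusted p = 1 in edgeR, from 0.00565 to 1 over the alternatives). RNA of the maternal seed coat is a candidate source: 9 of the 15 tested list members were among the maternally biased genes (one-sided Fisher exact p = 1.46e-09), and the list's median maternal share was 98.1% over 19 genes. The Fisher test takes genes as independent, but the estimated correlation of the list was 0.441, and camera with it gave adjusted p = 0.165. The list members also do not show the source of the other maternal calls. The plan did not say how to combine libraries, and the combined median was used after the medians of single libraries were known (71.4% over 5 genes in the LCM-titled library, 98.7% over 19 and 97.7% over 15 in the others). For part of the genes the same source was argued against: of 320 genes called without the LCM-titled libraries, 19, among them SDC, HDG9, MYB3R2 and AT1G59930, had more maternal reads in the LCM-titled endosperm library than 3 times the amount that its seed coat list allows (ratio of the list 0.19). That library is a single one of Col × Ler, so an ecotype effect is not excluded there, and the test takes the list to stand for the whole coat. TT10 makes up much of the list, with 452 of 1463 CPM in the LCM-titled library and 2900 of 5200 and 1490 of 2686 in the others. The test, a Poisson one, allows counting error only, while this library differed from the other pure ones by a chi-square per degree of freedom of 50.5 and 59.5. It argues against the coat only under these assumptions. An earlier criterion for this test was replaced, unrun, after the library summaries were seen.

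The next pattern is the gain of maternal reads by paternally biased genes in the fie and dme libraries. In fie 26 of 37 of them were more maternal, against 1322 of all 6728 genes (median log2 2.03 against 0.92). In dme the gain was not particular to these genes, with 18 of 39 against 3491 of 6980 (median log2 1.09 against 1.72). These sets were picked on the same pure libraries that serve as the reference, so part of a gain is built in. With the paternally biased genes taken from full endosperm, 9 of 28 were more maternal in fie (median log2 1.28) and 9 of 33 in dme (0.53). Seed coat RNA, scaled from the difference of full and pure endosperm, made up a median of 21.5% of the gain in maternal CPM in fie, and under 50% in 16 of 25 genes. In dme it made up 73.6%, and under 50% in 8 of 16 genes. Neither value met the bound set for or against this source, so seed coat RNA and a loss of maternal silencing cannot be told apart for these genes as a set. Nor can other differences from wild type: EPR1 took 0.0451% of the reads in dme and 0.00735% in fie, against 8.62% and 13.1% in pure replicates 2 and 3. The scaling takes the mutant seeds to be otherwise like wild type. It takes the difference of full and pure endosperm as seed coat RNA, though the labels do not say how these preparations differ. It also rests largely on TT10, with 39700 of the 57044 CPM of the list in dme and 19400 of 25120 in fie. The prediction was set to 0 where full endosperm had no more maternal CPM than pure endosperm. Such a 0 is not a measured absence from the seed coat, and these values enter both medians and the counts under 50%. VIM5 had 991 maternal CPM in fie against 51 in wild type, with 0 predicted in this way. In dme VIM5 gained 186 maternal CPM with 0 predicted, but AT3G14205 gained 199 with 305 predicted and ROS1 gained 30 with 140 predicted. Loss of maternal FIE or DME function stays an open biological explanation, with 1 library of 1 cross direction each.

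The last pattern is the higher maternal share of most genes in the dme library. Its seed coat list, at 57044 CPM, was 11 times that of pure replicate 2, of the same cross (5200 CPM, and 1463 in the LCM-titled library of that cross). The shifts from pure replicate 2 to dme and to full endosperm had a Spearman rho of 0.19 across 4742 genes, which are not independent replicates. The reads of pure replicate 2 were split at random between both shifts, so counting noise is not shared, but its other variation is and can give a positive rho by itself. The rho therefore decides nothing, and seed coat RNA stays open. Self-pollinated seeds as the whole cause were argued against: 18 of 39 paternally biased genes had a 95% upper bound under the floor of 66.5% that this would set. The floor takes self-pollinated and crossed seeds to express each gene at the same level, which was not tested. The argument holds only under that assumption, and the bounds cover counting error only. An earlier criterion for self-pollination, the median share of the endosperm list in dme, had measured 74.7% over 7 genes, below the 85% set for a cause, and was replaced by the floor after it was seen. An effect of the dme mutation itself was not tested.

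The 6 wild-type libraries of pure endosperm and embryo allow 10 splits into 3 and 3, too few for a share under 0.05. Most of the splits place both libraries of a set named alike on 1 side, unlike the real one. In the expression fit, where these sets are a block, such splits are not like comparisons. For expression the real split called 1992 genes and the highest other 0, so that 1 split called as many. For parental bias, fitted with 1 shared ecotype term, the real split called 39 genes and the highest other 4, so that 1 split called as many.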

How the results depend on the processing

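The use of full endosperm as the wild type was chosen after the results were seen. With at least 30 reads per cross direction there were 190 maternal and 25 paternal calls in pure endosperm, 25 maternal in embryo, 34 differences between endosperm and embryo, and 5 maternally biased genes less maternal in dme, where fewer genes were tested. With at least 1 read, embryo had 3 paternal calls. DESeq2 gave 155 and 28 calls in pure endosperm, 1162 and 24 in full endosperm, 24 maternal in embryo, and 1, 4 and 7 maternally biased genes less maternal in dme, fie and met1. The median ratio as the expected ratio gave 813 and 270 calls in full endosperm and 2 paternal in embryo. In dme it gave 1065 changed genes, with 7 paternally biased more and 39 maternally biased less maternal, in fie 628, 15 and 19, and in met1 72 with 2 paternally biased. Embryo had 4 paternal calls with only the libraries compared, 4 by exact binomial tests and 2 without the LCM-titled libraries. With the biased genes from full endosperm, 9 paternally biased genes were more maternal in dme and 9 in fie. Full endosperm as the wild type gave 14 maternally biased genes less maternal in dme, 16 paternally biased more and 22 maternally biased less maternal in fie, and 29 changes with 1 paternally biased gene more maternal in met1. Fisher tests, which compare libraries and not conditions, gave 2732 changes and 20 maternally biased genes less maternal in fie, and 1146, 23 and 14 paternally biased more maternal in met1. The cause was not tested except where named.

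Between tissues, the fit with no replicate block called 622 genes higher in embryo. Leaving out the LCM-titled libraries gave 1619 genes higher in endosperm, and full in place of pure endosperm 1839. Of 22 list calls by camera, 0 held with an estimated correlation. Fry, which tests whether the genes of a list move 1 way and compares them with no other genes, called 5 lists in pure endosperm, 2 in full endosperm, 3 in dme, 4 in fie and 2 between tissues.

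Leaving out 1 library at a time gave these lowest and highest counts. Pure endosperm had 48 to 332 maternal and 14 to 51 paternal calls, with 23 to 201 and 4 to 18 of strong bias. Full endosperm had 442 to 2096 and 10 to 54, and embryo 2 to 53 and 0 to 3. Differences between endosperm and embryo numbered 7 to 93, with 3 to 66 more and 4 to 28 less maternal. In dme 1871 to 3571 genes changed, 1847 to 3504 more and 24 to 67 less maternal, with 12 to 18 paternally biased more and 3 to 9 maternally biased less maternal. In fie 858 to 1527 changed, 821 to 1475 more and 29 to 61 less, with 15 to 26 and 5 to 16. In met1 100 to 282 changed, 91 to 248 more and 9 to 34 less, with 3 to 5 and 6 to 18. Endosperm had 555 to 1653 higher genes and embryo 460 to 1500. Embryo and its difference from endosperm could not be fitted without embryo replicate 3, the 1 embryo library of Ler × Col, nor full endosperm with only its own libraries.

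Some log2 values changed sign. With the median ratio as the expected ratio these were DME in full endosperm (-0.17) and, in dme, DME (-0.34), YUC10 (-0.30), AGL92 (-0.99), HDG3 (-1.01) and VIM1 (-0.36). Over the fits without 1 library, the lowest and highest values in full endosperm were -0.60 (without full replicate 1) and 4.54 for AGO9, -2.33 and 0.29 (without full replicate 2) for NRPD1, and -0.92 (without full replicate 2) and 2.08 for WOX8. In dme they were -0.50 (without pure replicate 2) and 2.32 for HDG3, and -2.79 and 1.31 (without pure replicate 2) for SDC. In dme AGL92 was at -0.43 by Fisher test. With full endosperm as the wild type SDC was at 1.77 in dme and 0.08 in fie. The cause was not tested.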

Other observations

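These values were picked after they were seen, and no test was run on them. Of 22 type I MADS genes, which encode transcription factors active in early endosperm, 12 had at least 10 allele reads in the dme library and 13 in the fie library. Their reads summed to 951 and 2420 CPM, against at most 33.5 CPM in each of the other 9 libraries. The endosperm list summed to 1006 CPM in the dme library and 926 in the fie library, and to 187717 in the met1 library, 87571 and 132666 in pure endosperm replicates 2 and 3, and 17219 in the LCM-titled one. Nearly all of the sum in met1 and pure replicates 2 and 3 was EPR1 (18.7%, 8.62% and 13.1% of reads), so a drop of the whole list is not shown. With at least 10 reads, 7 list members were measured in dme and 9 in fie, against 5 in met1 and in each pure library.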
